A study of Zea mays with 168 samples.

How the data were processed

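The study measured transcript levels in primary roots of maize (Zea mays) 3.5 days after germination, in 4 inbred lines and the 12 reciprocal hybrids between them, on cDNA microarrays read in 2 colours. A genotype is written with the line named first in the labels followed by the line named second, so that 005x250 and 250x005 are the reciprocal hybrids of the same pair and 005x005 is an inbred line. Per the labels' protocols, about 20 roots were pooled for each biological replicate, polyadenylated RNA was purified, and cDNA was labelled with Cy3 or Cy5. Per the series text, each RNA sample was an independent biological replicate, and samples were paired on slides by a scheme optimised for non-additive effects, with unequal numbers of replicates. In all, 168 channels of 84 slides were analysed here. Each channel is 1 sample, and the slide that both share was taken into account by working with their ratio.

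The deposited scanner tables hold 1 linear spot intensity per scan, and the deposited notes describe them as raw values of scans at rising photomultiplier gain. The scanner software and any earlier background subtraction are not given in the sources used here. The deposited value table holds log2 values for which, per the deposited notes, the authors chose 1 scan per channel and normalized it. The method is not given in the sources used here. Its column medians ran from 8.9 to 11.26, both channels of a slide had medians within 0.1 of each other on 82 of 84 slides and 1.48 apart on slides 288 and 289, and the values were not centred per spot. Each column is 1 channel, and which dye it holds was taken from the labels.

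The values of the scanner tables were found to lie in another row order than the identifiers beside them. After a rotation of the rows, 99.836% of spots had their best match in the value table at the same row, and the SD over spots of identifiers printed 12 times fell from 1.243 to 0.377 on the log2 scale. The rotation was used throughout, and each channel then had a median rank correlation of 0.9935 with its own column of the value table. In 8 channels the other channel of the same slide was closer. On slides 0 and 1 this held for both channels (0.871 with the own and 0.995 with the other channel, 0.958 and 0.972, 0.899 and 0.948, 0.776 and 0.994), so that an exchange of their channels, which would turn the sign of their ratios, is open and was not corrected. Both are among the 9 doubtful slides left out in 1 alternative. No sample was moved to another genotype. The labels conflict on dyes for 19 samples of 10 slides (932 to 999), where the label field names another dye than the title. The title was used, except for 1 sample of slide 930, where both titles name Cy3 and the label field gives Cy5. On these 10 slides all 20 channels of the titles' dyes were closer to their own column of the value table than to the other (lowest own 0.971, highest other 0.941). With the label field, the ratio and the order of its genotypes both turn on 9 slides. Each intensity stays with its genotype, so only the dye effect changes there. Slide 932 drops out, since both of its channels are then Cy3. An exchange of channels between the genotypes of these slides was not tested. Another 18 columns, of 2 slides that match no labelled sample, were not used.

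Between 3 and 7 scans per channel were combined. Of 991 scans, 14 in 10 channels were left out because their median rank correlation with the other scans lay more than 0.05 below the best. The rest were scaled linearly to the scan of highest gain, values above 45000 were dropped where a lower one was left, and the median was taken per spot. Slides 26 and 472, and slides 28 and 48, held nearly identical values (rank correlations of 0.9913 to 0.9989 in both channels, against a median of 0.6205 for samples of 1 genotype and dye). Each pair was averaged and counted once, which left 82 slides and 164 samples.

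Of 12160 spots, 190 without an identifier and 132 spots of the 11 identifiers printed 12 times were left out of the tests, with weight 0 in the loess fit. This left 11838 spots of 11431 identifiers. Spots that share an identifier were kept apart because their levels had a rank correlation of only 0.24 (402 identifiers with 2 or 3 spots). The identifier, and any symbol taken from it, may therefore be wrong for part of the spots. Intensities were corrected with limma's normexp (offset 50), and log2 ratios of Cy5 over Cy3 were normalized within each slide by loess (span 0.3). A linear model with 16 genotypes and a dye effect was fitted per spot over all slides, with 66 residual degrees of freedom and limma's moderated variances (prior degrees of freedom 11.11). Comparisons and tests were fixed before the data were examined, together with the first 7 alternatives named below. A spot was called at an adjusted p under 0.05 (Benjamini-Hochberg within each comparison). Levels of single groups are given as log2 channel levels with the SD over samples. These levels were rebuilt from each slide's loess-normalized log ratio and its mean log2 intensity, quantile-normalized between slides. They are not scanned intensities. They leave out the pairing on slides, so their differences need not equal the fitted ones. The number of arrays limits the precision of all values.

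Identifiers are those printed in the files. The reference table of assembly Zm-B73-REFERENCE-NAM-5.0 gave a symbol for 8 of them, and the files pair the others with no gene name. Tests of gene lists defined by gene descriptions had been planned with camera, and could not be run. The rule for named genes ranks called spots that have a gene name. No called spot had one, so the identifiers with the largest changes are given instead, at most 2 in each direction per comparison, chosen after their values were seen.

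The fit was tested on simulated log ratios with 200 of 11838 spots changed. The noise was first drawn independently, with the same SD on every slide for a given spot. For the mean of the hybrids against the mean of the lines, 94% of changes of 0.5 (log2) were recovered. For 250x005 against its parents, 29% of changes of 1 and 97% of changes of 2 were recovered. For 002x301 these shares were 57% and 99.5%, for the lines 005x005 and 250x250 24% and 94.5%, and for 005x250 against 250x005 12% and 93.5%. With whole slides' residuals drawn together, changes of 1 were recovered in 29.5%, 56%, 13.5% and 17.5% of spots, in the same order from 250x005 on. Neither simulation kept a wide spread with the slides that carry a genotype, so the recovery in the data may differ. The first simulation without a change gave no call in each of these comparisons. In 100 further simulations without a change, with whole slides' residuals drawn together and added after the data had been seen, 17 gave a call for 250x005 (at most 311 spots, 2 of them with 198 or more), 3 for 002x301 (at most 2), 5 for the lines 005x005 and 250x250 (at most 21) and 15 for 005x250 against 250x005 (at most 475). With whole slides' residuals drawn together, up to 105 unchanged spots were called beside real changes of 2 in 002x301.

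The alternatives chosen beforehand were no background correction, median centring, a separate-channel fit, the authors' value table, leaving out the dimmest 25% of spots, dyes taken from the label field, and a dye effect for each range of slide numbers. After the data and the small number of calls had been seen, 5 more were added: print-tip loess, array quality weights, both together, leaving out 9 doubtful slides, and 1 scan per channel. For named spots with a sample far from its group, the fit without that sample's slide was also added then. Smoothing over the slide surface, sign changes of single slides and principal components were also looked at after the data had been seen, and are not used for any value given here. Tools were R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.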

Results

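Transcript levels in maize primary roots were compared between 4 inbred lines and their 12 reciprocal hybrids. The lines were represented by 16 (002x002), 18 (005x005), 16 (250x250) and 19 (301x301) samples and each hybrid by 6 to 10, with nearly identical slides counted once. Signal was weak in many channels. The median spot was 1.895 times as bright as the median unnamed spot over all samples, with a range from 0.95 to 8.65. In hybrid samples a median of 50.2% of tested spots lay above the unnamed spots at the block edge (range 8.8% to 93%, n = 95), and in inbred samples 53.6% (range 5.9% to 89.9%, n = 69). This share differed between genotypes, from a median of 17.9% in 250x005 (n = 6) and 21.3% in 250x002 (n = 8) to 82.8% in 250x301 (n = 8).

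**Figure D1:**
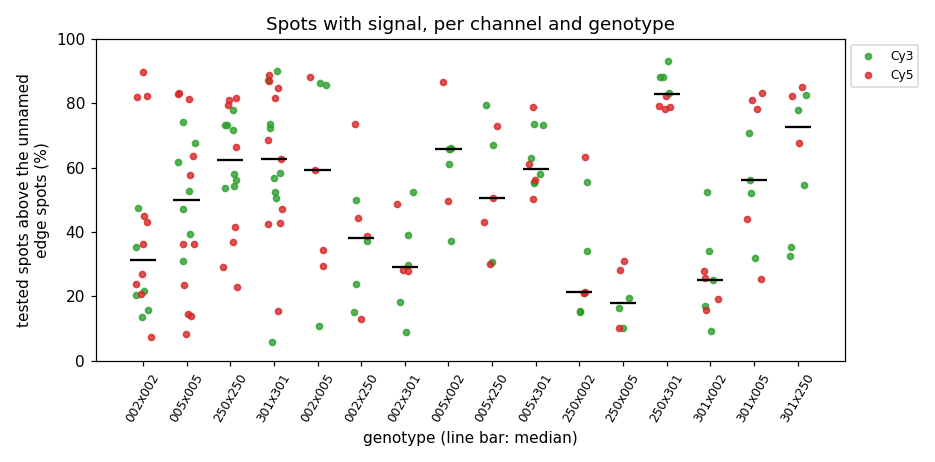
Share of tested spots above the 97.5th percentile of the unnamed edge spots (percent) for each sample, by genotype; points are samples, with nearly identical slides averaged, coloured by dye and bars are medians. The samples of 250x005 lie at 31% or below, and those of 250x301 at 78.2% or above.

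Log ratios of separate slides carrying the same pair of genotypes had little in common. The median correlation over spots was 0.005971 for 29 pairs of slides with the same dyes and -0.05803 for 50 pairs with swapped dyes. The sign had been turned for swapped dyes, so that both slides run in the same order of genotypes. A shared difference between the genotypes would then give a positive value in both cases, and the value for swapped dyes has the opposite sign. Print blocks accounted for a median of 25.31% of the variance of a slide's log ratios (range 6.253% to 64.09%). The median residual SD of a spot was 0.7306 on the log2 scale.

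The first comparison asked whether hybrids as a group depart from their parents. No spot of 11838 was called higher or lower in the mean of the 12 hybrids than in the mean of the 4 lines (limma, smallest adjusted p = 0.99), and 416 spots (3.5%) had an unadjusted p under 0.05. The median SE of this difference was 0.09, giving a 95% interval of 0.18 to each side, and all estimates lay within 1. AW257883 (LOC100279628) was 0.14 ± 0.09 (SE) higher in hybrids, AI987507 (LOC542198) 0.1 ± 0.07 and AW400087 (LOC100500995) 0.05 ± 0.06. Neither spot of AI665898 (LOC100191184, listed as a reticulon) departed from 0 by more than its SE, with values of 0 ± 0.08 and 0.07 ± 0.12. None of the 8 identifiers with a symbol was called in this or any other comparison. Levels of spots that share an identifier had a rank correlation of 0.24 over 402 identifiers with 2 or 3 spots, so the assignment of identifiers and symbols to spots is open.

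Each hybrid was then set against the mean of its own parents, the measure of non-additive expression. The most spots were called in 250x005, 198 in all, with 72 higher and the rest lower than the parental mean. AW018262 was 1.67 ± 0.32 (SE) higher on the log2 scale (adjusted p = 0.005 with limma), with a level of 10.01 ± 2.22 (SD, n = 6) in the hybrid, 8.28 ± 0.48 in 005x005 (n = 18) and 8.43 ± 0.43 in 250x250 (n = 16). Its mean level over all samples, 8.58, was among the lowest of the named spots. Whether this spot lay above the unnamed spots was not tested. BG841990 differed by -2.2 ± 0.49 (adjusted p = 0.016 with limma), at 7.34 ± 1.03 in the hybrid, 9.82 ± 1.47 in 005x005 and 10.92 ± 1.09 in 250x250. The share of higher spots among the calls, 36.4%, was 59.8% without background correction, 64.2% with the authors' values and 15.8% with median centring. BG842222 differed by 1.54 ± 0.27, and without slide 19 by 1.17 ± 0.28 (adjusted p = 0.13 with limma), with a level of 10.09 ± 1.43 (SD, n = 5) in the hybrid in place of 11.54 ± 3.77 (n = 6). BM073560 differed by -2.15 ± 0.53, at 7.46 ± 0.7 in the hybrid. For this spot and BG841990 the hybrid had the lowest level of all genotypes, and whether these levels lay above the unnamed spots was not tested. Without slide 19, which carries 250x005 in a Cy5 channel at 0.95 times the unnamed spots, no spot was called for this hybrid, and without the 9 doubtful slides 3 were, 2 of them among the 198.

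In 002x301, 6 spots were higher and 10 lower than the parental mean. BM337438 was 1.84 ± 0.39 higher (adjusted p = 0.026 with limma), at 9.26 ± 2 (SD, n = 8) in the hybrid, 8.72 ± 1.4 in 002x002 (n = 16) and 7.56 ± 1.29 in 301x301 (n = 19). Its mean level over all samples, 7.79, was the lowest of the named spots, and whether it lay above the unnamed spots was not tested. BG873736 differed by 1.41 ± 0.33, AI691771 by -1.31 ± 0.26 and AI691763 by -1.22 ± 0.27, although their unpaired levels lay close to the parental mean, 0.03, -0.17 and -0.23 from it. Without slide 932, AI691771 differed by -1.43 ± 0.27 (adjusted p = 0.011 with limma). Its level in the hybrid was then 8.52 ± 1.03 (SD, n = 7), in place of 9.06 ± 1.8 (n = 8). Over the 17 spots named for a call in any comparison, the unpaired difference had the sign of the fitted one for all 17 and was smaller than the SD of the first genotype for 11. Of the calls 37.5% were higher, against 82.8% with print-tip loess. Of the 16 calls, 6 were kept with the dyes of the label field, which conflict with the titles on 10 slides. Median centring in place of loess gave 0 calls, and leaving out the doubtful slides gave 0.97% of the tested spots in place of 0.14%, with all 16 among them. BM078327 was 1.37 ± 0.24 higher in 005x250 (adjusted p = 0.0022 with limma), BG842449 differed by -1.81 ± 0.35 in 250x002 (adjusted p = 0.022) and BG842803 by -1.12 ± 0.22 in 301x002 (adjusted p = 0.023). Each was the single call of its hybrid, and each was lost with array quality weights. Without slide 558, BG842803 differed by -1.04 ± 0.23 (adjusted p = 0.31 with limma).

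In the other 7 hybrids limma called 0 spots. Their counts at an unadjusted p under 0.05 were 38 in 002x005, 919 in 002x250, 177 in 005x002, 368 in 005x301 and 57 in 250x301, and in 301x005 and 301x250 1% and 1.2% of the spots passed it. Over the 12 hybrids the median SE ran from 0.244 (005x301) to 0.313 (250x005). The fit took a common variance per spot for all slides, although the SD of log ratios ran from 0.2793 to 1.588 over slides. These SEs therefore do not reflect the noise of each hybrid's own slides. Without differences about 5% of spots would pass the unadjusted threshold, against 0.3% seen in 002x005 and 17% in 250x005. Counts of calls may thus not be equally reliable between comparisons. With the authors' values 5600 spots were called for 005x301, and 0 once slides 288 and 289 were left out, on which the medians of both channels lay 1.48 apart in the authors' values.

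Expression above the higher or below the lower parent was not called by limma for any of 142056 combinations of spot and hybrid, with 2209 at an unadjusted p under 0.05. The separate-channel fit gave 75 and the authors' values gave 9. The F test of whether the deviation from the parents depends on the cross also called 0 spots (smallest adjusted p = 0.28, 981 at an unadjusted p under 0.05), against 1.4% of spots with the separate-channel fit and 1.1% with the authors' values. Neither result was counted in the authors' values without slides 288 and 289.

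**Figure D2:**
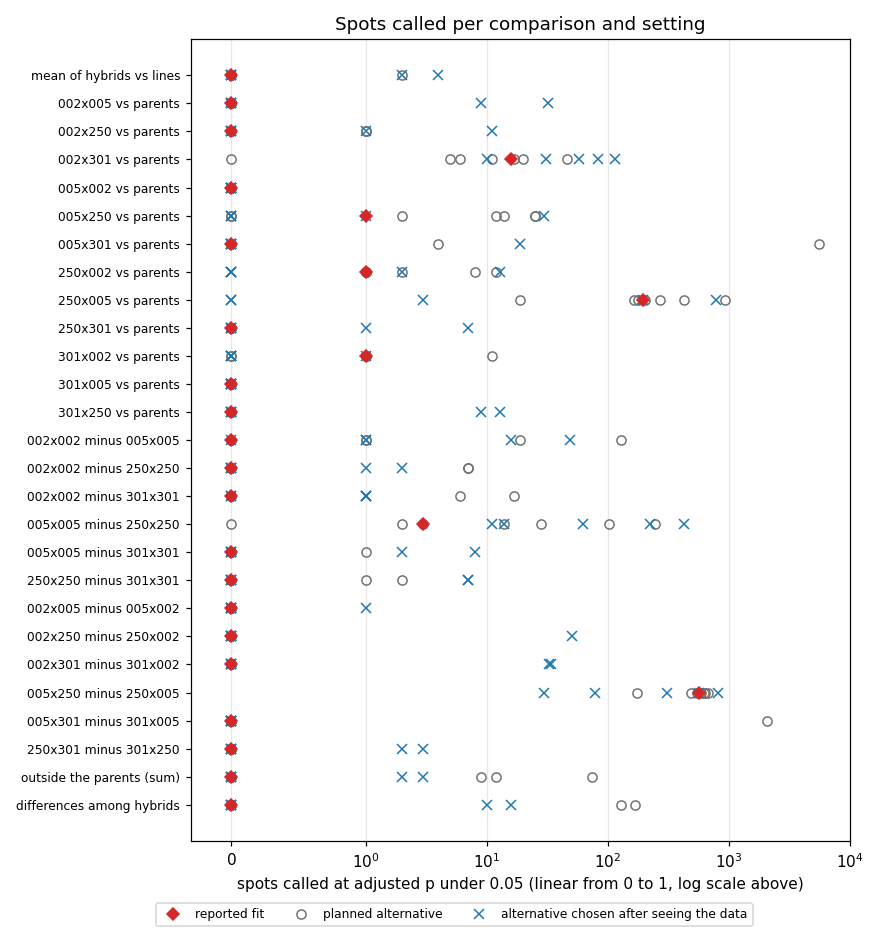
Spots called (adjusted p under 0.05) for each comparison on an axis that is linear from 0 to 1 and logarithmic above; diamonds are the reported fit, circles settings chosen beforehand and crosses alternatives chosen after seeing the data. The reported fit gives 571 for 005x250 minus 250x005, 198 for 250x005 and 16 for 002x301, and at most 3 elsewhere.

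Differences between the parental lines were compared for the 6 pairs. Between 005x005 and 250x250, 3 spots were called, all lower in 005x005. AI834114 differed by -1.72 ± 0.34 (SE, adjusted p = 0.037 with limma) and AI622244 by -1.35 ± 0.28 (adjusted p = 0.043). Their channel levels were 9.6 ± 0.8 (SD, n = 18) against 9.87 ± 0.58 (n = 16) for AI834114 and 10.07 ± 0.84 against 10.69 ± 1.05 for AI622244, so that the differences between unpaired levels were within the SD. All 3 calls were kept with print-tip loess, with array quality weights and without the doubtful slides, and lost with median centring. In place of 0.025% of the spots, 2.1% were called with the separate-channel fit, 1.9% with array quality weights, 3.6% with these and print-tip loess and 0.86% with the authors' values. For the other 5 pairs limma called 0 spots, with 577 (002x002 and 005x005), 530 (002x002 and 250x250), 491 (002x002 and 301x301) and 605 (250x250 and 301x301) at an unadjusted p under 0.05, and 1.2% of the spots for 005x005 and 301x301. The separate-channel fit called 1.1% of the spots between 002x002 and 005x005.

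**Figure D3:**
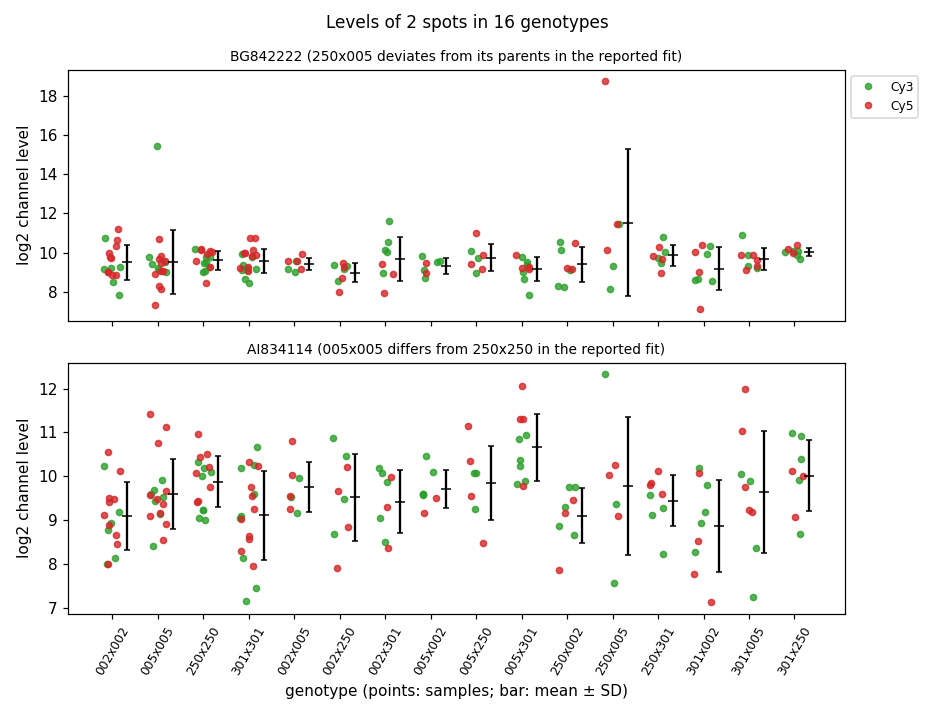
Log2 channel levels of BG842222 (top) and AI834114 (bottom) in the 16 genotypes; points are samples coloured by dye, and bars are the mean with SD. For BG842222 the mean of 250x005, 11.54 ± 3.77 (n = 6), includes 1 sample at 18.76, a normalized value from a channel at 0.95 times the unnamed spots.

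Reciprocal hybrids share both parents and differ in which line is named first. Between 005x250 and 250x005, 571 spots were called, 77.9% of them higher in 005x250, a share of 62% without background correction and 56.8% with the authors' values. AJ507106 differed by 3 ± 0.93 (SE, adjusted p = 0.045 with limma), at 14.74 ± 1.09 (SD, n = 7) in 005x250 and 12.56 ± 1.91 (n = 6) in 250x005, and AI461544 by 2.66 ± 0.82. Without slide 46 the difference of AJ507106 was 4.72 ± 1. AW042394 differed by -2.2 ± 0.47 (adjusted p = 0.0034 with limma), at 9.18 ± 0.68 and 10.93 ± 2.35, and AI691683 by -2.15 ± 0.48. Both rested on slide 46, without which they differed by -0.49 ± 0.36 and -0.74 ± 0.45 (adjusted p = 0.42 and 0.32 with limma) and had levels of 9.99 ± 0.6 and 8.93 ± 0.3 in 250x005 (SD, n = 5). Of the 571 spots, 8 were called in each of the 13 settings, and 77 without the doubtful slides. The 250x005 channels also had the fewest spots above the unnamed spots (median 17.9%, against 50.5% in 005x250), and without slides 18 and 19 the count was 30. For the other 5 reciprocal pairs limma called 0 spots, with 56 (002x005), 900 (002x250), 597 (002x301), 274 (005x301) and 177 (250x301) at an unadjusted p under 0.05, each against its reciprocal. The authors' values gave 2061 calls between 005x301 and 301x005, and 0 without slides 288 and 289.

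Slides fall into 4 ranges of slide numbers, and the comparisons that could be estimated were repeated within each. The 29 slides of the lowest range gave 398 calls for 250x005, 290 for 005x250 against 250x005 and 140 for 005x005 against 250x250. It also gave 15 for 005x250, 2 for 005x301, 1 for 002x250 and 5 for 005x301 against its reciprocal. The range that starts at 273 (18 slides) gave 10 calls for 002x250, 1 for 002x250 against its reciprocal, and 1.1% of its spots for 002x002 against 250x250, a comparison with 0 calls over all slides. The range that starts at 916 (22 slides) gave 11 calls for 002x250 and 0 for its other comparisons, among them 005x005 against 250x250 and 002x301, and the range that starts at 471 (13 slides) gave 0 calls in each comparison that could be estimated there. The comparison of 250x005 with its parents, and that of 005x250 with 250x005, could be estimated in the lowest range alone. That range holds all samples of 250x005 and slides 18 and 19. Its calls for these 2 comparisons are therefore not a separate repeat of those over all slides.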

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

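The tests that leave out slides 18 and 19 were chosen after the results were seen, as were those without slide 46, the limit for unnamed spots and the spots examined for single samples.

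The deviation from the shared parents differed between 005x250 and 250x005 at 571 spots by a test of the difference itself. Leaving out slides 18 and 19, whose Cy5 channels lay at 1.02 and 0.95 times the unnamed spots, left 30 calls, and for 250x005 against its parents 1 in place of 198. Without slide 19 alone the reciprocal count was 21.9% of its value with all slides and that for 250x005 was 0, and without slide 18 alone the counts were 210 and 291. Slides 44 and 46 carry both hybrids with opposite dyes. Of the 861 spots called without these direct slides, 77.7% moved the same way on slide 44 and 68.6% on slide 46, so a real difference between the hybrids may underlie part of the pattern, while most of the calls were lost without slides 18 and 19. The fit that called the 861 spots still held slides 18 and 19. On the direct slides the 250x005 channel lay at 1.47 times the unnamed spots (slide 44) and at 1.01 times (slide 46). Whether this low signal of 250x005 plays a part was not tested. Fewer slides also leave less power, so the lost calls do not show that these spots did not differ.

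Random regroupings of the samples gave as many spots in 4 of 100 splits for the reciprocal difference (real 571, highest other 704) and in 3 of 100 for 250x005 against its parents (real 198, highest other 690). Each share was under 5% taken singly. Since 27 results were examined in this way, and high counts also arose without any change, chance was not excluded. The regroupings could also put the same genotype in both channels of a slide, which no real slide has. In 100 simulations that drew whole slides' residuals together, chosen after the results were seen, the highest count was 475 for the reciprocal difference and 311 for 250x005, with 2 of 100 at 198 or more. These simulations moved residuals between slides at random, so they did not keep a wide spread with the slides that carry a genotype. In the data, slide 18 carries 005x250 and slide 19 carries 250x005. Their log ratios had SDs of 1.56 and 1.59, against a median of 0.7296 over slides. The simulated counts may therefore be too low for these comparisons. The highest splits lie above the simulated counts, and the reason was not tested.

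With the authors' values 5600 spots, 47% of those tested, were called for 005x301 against its parents. Slides 288 and 289 may be the cause, since the count was 0 without them. On each of them the deposited values of 1 channel follow neither channel of that slide closely. The medians of both channels lie 1.48 apart, against at most 0.1 on the other 82 slides. They were 10.84 (Cy3) and 9.36 (Cy5) on slide 288, and 10.83 and 9.35 on slide 289. Whether these values follow a channel of the other slide was not examined. No biological explanation was tested.

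Of 31 groups examined for a sample far from the others, 10 had one, where chance gives about 1 in 20. Many of these spots had been picked for large changes, so the share is not a rate for all spots. The ratio of the median to the unnamed spots was 4.08 in 250x002 replicate 78 (group median 1.8), 2.38 in 250x005 replicate 14 (1.18), 6.87 in the Cy3 sample of 250x301 on slide 916 (3.46) and 8.23 in 301x005 replicate 86 (3.21). For BG842222 in 250x005 the normalized log2 level was 18.76 on slide 19 (group median 10.79), in a channel at 0.95 times the unnamed spots. For other single spots the log2 level was 12.84 for AI691771 in 002x301 on slide 932 (8.71) and 7.01 for BG842803 in 301x002 on slide 558 (9.61). On slide 46 it was 12.42 for AJ507106 in 005x250 (14.87), and 15.6 for AW042394 and 16.53 for AI691683 in 250x005 (10.18 and 9.08). Without slide 46 the last 2 spots were no longer called between the reciprocal hybrids.

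Among spots with no identifier, 21 of the 30 inside the print blocks lay above the 97.5th percentile of the 160 at the block edge, the brightest at 4.31 (log2) above the channel median. What they hold is not given in the sources used here.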

How the results depend on the processing

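The alternatives with print-tip loess, array quality weights, both together, without the doubtful slides, with 1 scan per channel and, for single named spots, without slide 19, 46, 558 or 932 were chosen after the results were seen, and the others beforehand. Whether weak signal over the unnamed spots limits the comparisons was not tested directly, and leaving out the dimmest 25% of spots moved 3 of 27 counts. Of the 27 named spots, 21 were left in that fit. Simulations with independent noise were made for 250x005, 002x301, the lines 005x005 and 250x250, and 005x250 against 250x005. A change of 1 (log2) was recovered there in 12% to 57% of spots, and in 13.5% to 56% with whole slides' residuals drawn together. Changes in other hybrids, line pairs or reciprocal pairs were not simulated. Of 324 counts of called spots under the alternatives, 211 stayed within 1.5 times the reported count or at 0, and the rest did not. Most reported counts were 0, so many of the 211 were 0 in both fits. With array quality weights 18 of 27 counts moved, among them every reported count above 0. Of 324 values of named spots, 228 kept their direction and side of the threshold, 71 kept their direction and were no longer called, and 25 changed sign. Gene list tests and their alternatives were not run, since the identifiers have no descriptions. No paired analysis was possible because replicate numbers are not shared between genotypes, and the slide that pairs samples is already in the ratio. Counts are given below as the share of tested spots called, where 1 spot of 11838 is 0.0084%. Without the dimmest 25% the shares are of 8878 spots. For values outside the parents they are of 142056 combinations of spot and hybrid, so the same share stands for more calls. The reported shares are 4.8% for 005x250 minus 250x005, 1.7% for 250x005, 0.14% for 002x301 and 0.025% for 005x005 minus 250x250. A genotype alone stands for its comparison with the mean of its parents, and the cause of each change was not tested except for slides 18, 19, 288 and 289.

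Without background correction, the shares were 0.0084% for 002x250 and 002x002 minus 005x005, 0.39% for 002x301, 0.21% for 005x250, 0.1% for 250x002, 3.6% for 250x005. For values outside the parents 0.0084% of the combinations of spot and hybrid were called. Further shares were 0% for 301x002, 0.12% for 005x005 minus 250x250, 0.017% for 250x250 minus 301x301. Median centring gave 0% for 002x301, 005x250, 301x002 and 005x005 minus 250x250, 0.16% for 250x005. The separate-channel fit gave 0.0084% for 002x250 and 005x005 minus 301x301, 0.042% for 002x301, 0.017% for 005x250, 0.034% for 005x301, 0.068% for 250x002. Further shares were 7.8% for 250x005, 1.1% for 002x002 minus 005x005, 0.059% for 002x002 minus 250x250, 0.14% for 002x002 minus 301x301, 2.1% for 005x005 minus 250x250. Further shares were 0.053% for values outside the parents, 1.4% for the F test. The authors' values gave 0.017% for the mean of hybrids and 250x002, 0.0084% for 002x250, 0% for 005x250, 47% for 005x301, 0.093% for 301x002. Further shares were 0.16% for 002x002 minus 005x005, 0.059% for 002x002 minus 250x250, 0.051% for 002x002 minus 301x301, 0.86% for 005x005 minus 250x250, 1.5% for 005x250 minus 250x005. Further shares were 17% for 005x301 minus 301x005, 0.0063% for values outside the parents, 1.1% for the F test. The last 2 of these were not computed without slides 288 and 289. Without the dimmest 25% of spots, the shares were 0.28% for 005x250, 0.011% for 002x002 minus 005x005, 0.32% for 005x005 minus 250x250. Dyes from the label field gave 0.051% for 002x301, 0.1% for 005x250, 0.0084% for 250x250 minus 301x301. A dye effect for each range of slide numbers gave 0.12% for 005x250.

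Among the alternatives chosen after seeing the data, the shares moved as follows. Print-tip loess gave 0.017% for the mean of hybrids and 002x002 minus 250x250, 0.49% for 002x301, 0.11% for 250x002, 6.6% for 250x005, 0% for 301x002. Further shares were 0.0084% for 002x002 minus 005x005, 0.53% for 005x005 minus 250x250, 0.059% for 250x250 minus 301x301, 0.0021% for values outside the parents. Array quality weights gave 0.076% for 002x005, 0.0084% for 002x250, 250x301 and 002x002 minus 301x301, 0.26% for 002x301, 0% for 005x250, 250x002, 250x005 and 301x002, 0.11% for 301x250. Further shares were 0.14% for 002x002 minus 005x005 and the F test, 1.9% for 005x005 minus 250x250, 0.017% for 005x005 minus 301x301, 0.059% for 250x250 minus 301x301, 0.28% for 002x301 minus 301x002. Further shares were 2.6% for 005x250 minus 250x005, 0.025% for 250x301 minus 301x250. Both together gave 0.034% for the mean of hybrids, 0.27% for 002x005, 0.093% for 002x250, 0.084% for 002x301 and the F test, 0% for 005x250, 250x005 and 301x002. Further shares were 0.16% for 005x301, 0.017% for 250x002 and 250x301 minus 301x250, 0.059% for 250x301, 0.076% for 301x250, 0.41% for 002x002 minus 005x005. Further shares were 3.6% for 005x005 minus 250x250, 0.068% for 005x005 minus 301x301, 0.0084% for 002x005 minus 005x002, 0.43% for 002x250 minus 250x002, 0.29% for 002x301 minus 301x002. Further shares were 0.25% for 005x250 minus 250x005. Without the doubtful slides, the shares were 0.97% for 002x301, 0% for 005x250 and 250x002, 0.025% for 250x005, 0.0084% for 002x002 minus 250x250 and 002x002 minus 301x301, 0.12% for 005x005 minus 250x250. Further shares were 0.67% for 005x250 minus 250x005. With 1 scan per channel, the shares were 0.7% for 002x301, 0.25% for 005x250, 0% for 250x002 and 301x002, 0.0084% for 002x002 minus 005x005 and 002x002 minus 301x301, 0.093% for 005x005 minus 250x250. Further shares were 0.0014% for values outside the parents.

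For spots with a symbol, the mean of hybrids against lines changed sign in 25 cases, with no call before or after. Without background correction, the values were 0.03 for AI665898 (spot 8746), 0.01 for AI691686 (spot 5346), 0 for AI691686 (spot 5586) and 0 for AI714808. Median centring gave 0.11 for AI691686 (spot 5346) and -0.01 for AW400087. The separate-channel fit gave 0.01 for AI691686 (spot 5346) and 0.01 for AI714808. The authors' values gave -0.01 for AI691686 (spot 5586) and -0.01 for AI901738. Dyes from the label field gave 0.01 for AI665898 (spot 8746) and 0 for AI691686 (spot 5346). Print-tip loess gave 0.07 for AI691686 (spot 5346) and 0.01 for AI714808. Array quality weights gave -0.01 for AI665898 (spot 11647), -0.03 for AI691686 (spot 5586) and 0.05 for AI714808. Both together gave 0.02 for AI665898 (spot 8746), -0.02 for AI665898 (spot 11647), 0.05 for AI691686 (spot 5346) and 0.07 for AI714808. Without the doubtful slides, the values were 0.03 for AI691686 (spot 5346) and 0.01 for AI714808. With 1 scan per channel, the values were 0.03 for AI665898 (spot 8746) and 0.02 for AI691686 (spot 5346).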

Other observations

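The use of print-tip loess with slides scaled to equal spread was chosen after the usual loess had shown no recurrence, and the test of the residual spread under it and the values by reciprocal pair were chosen after their results were seen. The bounds for the other covariance tests were set before. A covariance was counted as present when under 5 of 100 regroupings of the samples, the real one included, gave as large a value, and a value within the regroupings does not show that the effect is absent.

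A test of whether genotype differences recur used the covariance of fitted levels between 2 equal parts of the slides, averaged over 10198 spots and 10 divisions of the slides. With the loess used for the report, differences between the 4 lines had a covariance of -0.00808 (91 of 100 regroupings as large, highest other 0.0155) and differences between the 12 hybrids 0.00332 (36 of 100, highest other 0.0278). Genotype labels lowered the residual mean square by 0.78%, and 30 of 100 regroupings did as well (best other 3.09%). With print-tip loess and scaled slides the covariance was 0.048 for the lines (4 of 100, highest other 0.0648), 0.0401 for the hybrids (7 of 100, highest other 0.0671), and the residual mean square fell by 3.56% (2 of 100, best other 3.88%). This may reflect differences between the lines that the usual loess leaves covered, as a hypothesis from 1 of 2 normalizations and from 10 tests. Print-tip loess and the scaling of slides were changed together, so which of them matters was not separated.

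Whether hybrids follow the mean of their parents was tested in the same way, and neither covariance passed the bound. With the usual loess the parental mean had a covariance of -0.0022 with itself between the parts. Hybrids could therefore not have been seen to follow it there. With print-tip loess and scaled slides the parental mean had a covariance of 0.0131 with itself. The covariance of hybrids with the parental mean was -0.00423 with the usual loess (98 of 100, highest other 0.0051) and 0.00819 with print-tip loess (6 of 100, highest other 0.0138). That a hybrid resembles the line named first was tested in the same way and gave -0.0202 (100 of 100, highest other 0.0223) and -0.0648 (98 of 100, highest other 0.0703), values with the opposite sign. By pair, 005x250 and its reciprocal gave the lowest values, -0.112 and -0.288, and 002x301 and its reciprocal gave 0.0299 and 0.0847. Without the doubtful slides, which include slides 18 and 19, the first pair gave -0.108 and -0.325. The second pair then gave 0.0433 and 0.0801. Line differences themselves had a covariance of -0.0162 between the parts with the usual loess, so a resemblance could not have been seen there. With print-tip loess and scaled slides they had 0.096. No explanation for the negative sign was tested.

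Splits of the samples at random gave as many spots in 9 of 100 cases for 002x301 (real 16, highest other 402), 23 for 005x250 (real 1, highest other 1487), 26 for 250x002 (real 1, highest other 0.92% of spots), 12 for 301x002 (real 1, highest other 237) and 6 for the lines 005x005 and 250x250 (real 3, highest other 243), so chance could not be excluded for these. Where the real count was 0, all 100 splits gave as many. The highest count of another split was then 30 for the mean of hybrids, 615 for values outside the parents and 4 for the F test. Against the parents it was 595 for 002x005, 354 for 002x250, 430 for 005x002, 27 for 005x301, 235 for 250x301, 17 for 301x005 and 2 for 301x250. Between lines it was 89, 240 and 1 for 002x002 against 005x005, 250x250 and 301x301, 66 for 005x005 against 301x301 and 96 for 250x250 against 301x301. For reciprocal pairs it was 1 for 002x005, 178 for 002x250, 194 for 002x301, 19 for 005x301 and 4 for 250x301. Counts several times the real one would also arise from a structure of the samples, which was not tested. In 100 simulations without a change that drew whole slides' residuals together, chosen after the results were seen, the highest count was 933 for 005x250, 2 for 002x301, 0.88% of spots for 250x002, 58 for 301x002 and 21 for the lines 005x005 and 250x250.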
